A study of Mus musculus with 36 samples.

How the data were processed

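The study measured polyadenylated RNA in kidneys of male C57BL/6 mice kept in 12 h of light and 12 h of darkness and fed either normal chow or a high-fat diet ad libitum from 6 weeks of age. The labels give 16 weeks for the harvest. Zeitgeber time (ZT) counts hours from lights on. Kidneys were taken at ZT0, 4, 8, 12, 16 and 20 from 3 mice per diet and time, which gives 36 libraries in 12 groups. Groups were read from the sample labels. The times are those of the titles and descriptions. In all 36 labels the tag that holds the diet names ZT3, which is none of the 6 times, and the sources used here do not say why.

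The deposited values are FPKM (fragments scaled to transcript length and to the mapped fragments of the library), 1 table per diet with the same 24883 rows. Per the submitters' processing notes, CASAVA 1.8.2, Bowtie and Cuffnorm were used with the mouse build mm10; the versions of Bowtie and Cuffnorm are not given in the sources used here. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a TruSeq RNA kit. FPKM values are not counts, so no count model was used. Rows of symbols that occur more than once (817 rows of 280 symbols) were left out because they could not be told apart. No other column of values was left unused.

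Total reads are not in the files. Relative depth was estimated from the step between low FPKM values of 2525 rarely detected genes; 88.9% of these low values lay within 0.05 of a whole multiple of the gene's smallest value. Relative depth ranged from 0.324 to 1.391 across libraries. It was 1.007 ± 0.255 (SD, n = 18) under normal chow and 0.915 ± 0.281 (SD, n = 18) under the high-fat diet (two-sided permutation test, p = 0.308). The shallowest libraries have the largest counting error at low values, and absolute depth stayed unknown.

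Before the data were examined, the tests, gene lists, named-gene rule and first set of alternatives were fixed. The level comparison required both tables to share a scale, set as mean median log2 ratios within 0.05 of each other over 9752 genes with FPKM of at least 1 in all libraries. These means were 0.02 for normal chow and -0.01 for the high-fat diet, so the comparison was made. The sources used here do not state whether 1 Cuffnorm run made both tables, so a difference between runs would not be separable from diet in the level comparisons. Values were tested as log2(FPKM + 0.5) for the 11144 genes with a mean FPKM of at least 1, with limma 3.58.1 in R 4.3.3 and a mean-variance trend. Fold changes are on this scale, which understates the change of low genes. The Benjamini-Hochberg threshold was 0.05.

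Rhythm within a diet was the F test of a cosine and a sine term with a period of 24 h over its 18 libraries. A difference in rhythm was the F test of the diet by cosine and diet by sine terms over all 36. Levels were compared in a model with 12 group means, as the mean of the 6 high-fat groups minus that of the 6 normal chow groups, and at each time. Phase and amplitude differences were medians over genes rhythmic across both diets pooled at an adjusted p under 0.01, with diet labels permuted within time after centring. The permutation p used 99 random relabellings plus the actual labels, 100 groupings in all, so 0.01 is the smallest p they can give. The median over the clock genes alone was chosen after the data were seen, although the list was fixed before. Gene lists, 38 in all of which 35 had at least 4 measured genes, were tested with two-sided Fisher's exact tests for rhythm, and for level with limma's camera (preset correlation of 0.01, and an estimated one) and fry. Genes in a list are not independent replicates.

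The named genes were all measured core clock genes and, per diet, the 10 non-clock genes with the largest fitted peak-to-trough difference among rhythmic genes with mean FPKM of at least 5. For a difference in rhythm up to 10 genes per direction of amplitude were named. For level, the rule took the 10 highest and 10 lowest changes with the same sign at 5 or more times, and at each time 2 genes per direction by p. Up to 4 members by p were named per list. Unnamed gene models were left out except at single times. Some genes that this rule takes are not reported here, although they stayed in every test and count. Coordinates are those of GENCODE M21 on GRCm38, the assembly of mm10, counted from 1.

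Alternatives fixed beforehand were other pseudocounts, filters, rescalings, a robust prior, a replicate block, a rank test, time as a factor, a fit over all 36 libraries, other gene sets for phase and amplitude, and leaving out each library in turn. Alternatives added after the data were seen were removal of each library's trend over transcript GC content, the same with the block, leaving out 4 libraries with adrenal transcripts, an adipocyte score as covariate, leaving out ZT0 and ZT4, and a term that alternates between consecutive times. The fits of rhythm, difference in rhythm, level, phase and alternation, and the rank test, were tested on simulated data with all 11144 genes. The list tests, the depth estimate, the rescalings and the corrections were not. Among called genes, 7.1% for level and 5.8% for rhythm within a diet held no simulated change. These shares were 3.4% for a difference in rhythm, 5.2% by the rank test and 7.5% for alternation. Rhythms with a peak-to-trough difference of 1 on the log2 scale were called in 94% of cases within a diet, and 78% of rhythms of that size lost under 1 diet were called different. For a difference of 0.5 these shares were 50% and 34%. A peak moved by -1.5 h at a difference of 2 was called different in 67% of cases. The simulated noise was independent between genes, so it held no trend shared by the genes of a library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.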

Results

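Kidney transcripts were measured by RNA sequencing in mice on normal chow or a high-fat diet at 6 times of day, with 3 mice per diet and time. The title asks how the diet changes daily cycles of the kidney, so rhythms within each diet, differences between those rhythms, and differences in level were compared in turn. Values are FPKM, and relative depth ranged from 0.324 to 1.391 between libraries. No pair of libraries held identical values.

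Transcripts of neighbouring tissues differed between libraries. Cyp21a1, an adrenal steroid hydroxylase, reached 1346 FPKM in the normal chow library of ZT0 replicate 5, 262 and 163 FPKM in ZT4 replicates 2 and 3, and 20.2 FPKM in ZT16 replicate 4. Its highest value in the remaining libraries was 0.255 FPKM. Adipoq, which encodes the fat hormone adiponectin, ranged from 5.82 to 114 FPKM under normal chow and from 0.0852 to 69.8 FPKM under the high-fat diet. It was 0.0852 FPKM in the high-fat ZT12 replicate 5 and 0.0963 FPKM in ZT20 replicate 4. The trend of values over transcript GC content ranged from -0.37 to 0.42 log2 per 10 points of GC, both extremes being normal chow libraries of ZT4.

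**Figure D1:**
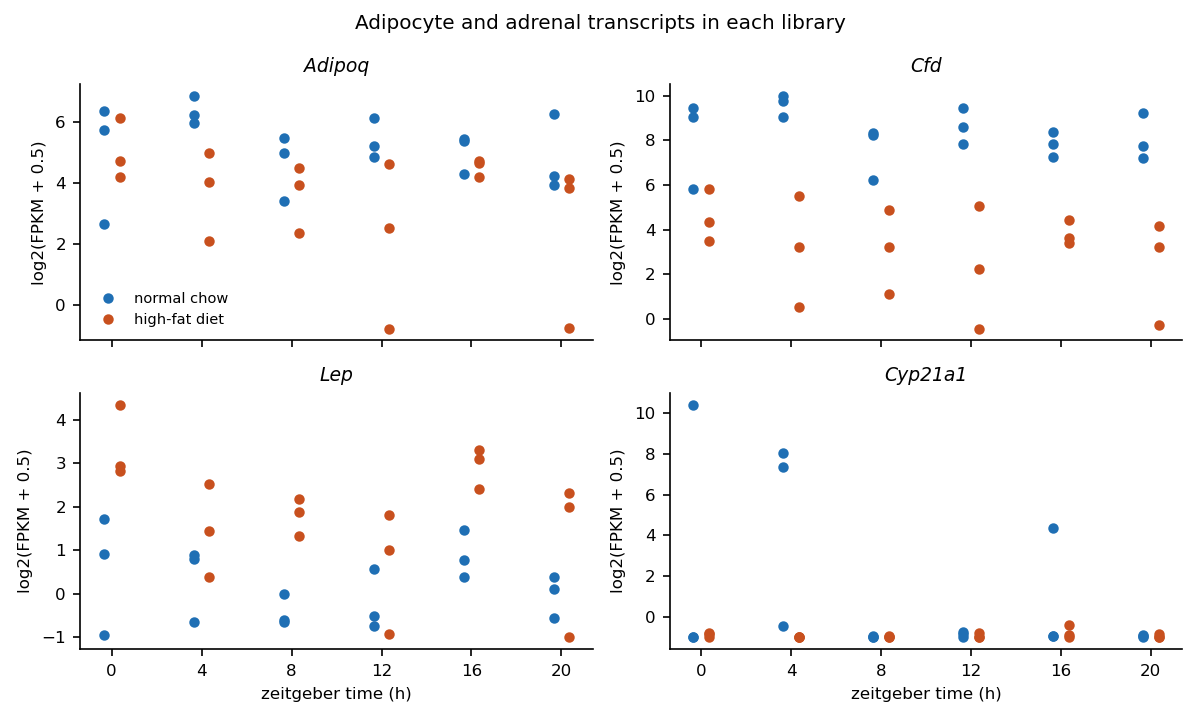
Log2(FPKM + 0.5) of 3 adipocyte transcripts (Adipoq, Cfd, Lep) and the adrenal Cyp21a1 against zeitgeber time in h, 1 point per library. Cyp21a1 stands out in 4 normal chow libraries, and Cfd lies lower under the high-fat diet.

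**Figure D2:**
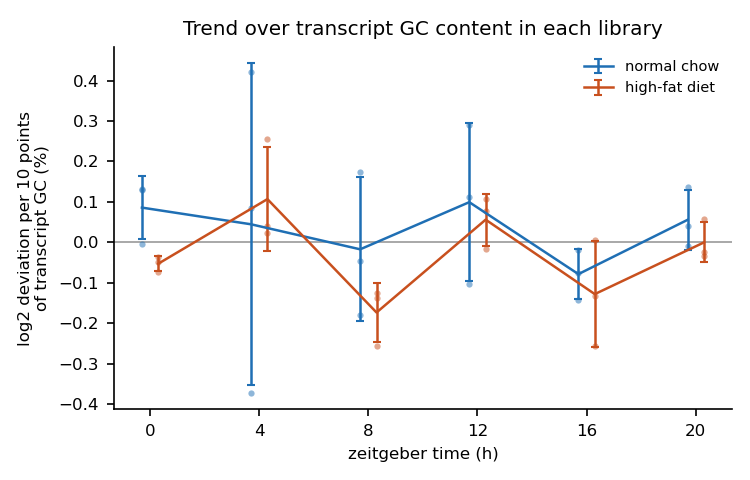
Slope of each library's log2 deviation over transcript GC content, per 10 points of GC, against zeitgeber time in h. Points are libraries, lines join means of 3 and bars are SD. The normal chow libraries of ZT4 span -0.37 to 0.42.

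The core clock cycled under both diets. Arntl, which encodes the transcription factor BMAL1, changed 14.1-fold from trough to peak under normal chow and 10.96-fold under the high-fat diet (limma, adjusted p = 2.77e-10 and 9.97e-09, n = 18 each). Its mean was 9.28 ± 0.458 FPKM (SD, n = 3) at ZT0 and 0.316 ± 0.152 FPKM at ZT12 under normal chow. Nr1d1, a repressor of Arntl, changed 15.1-fold and 13.0-fold with peaks at 6.77 ± 0.340 h and 5.50 ± 0.232 h (SE). Ciart, a further clock repressor, changed 18.5-fold and 19.8-fold. Of 14 measured clock genes 11 were rhythmic under normal chow and 13 under the high-fat diet, or 12 and 14 adjusted over the list alone (Fisher's exact test, adjusted p = 3.01e-09 and 6.93e-13).

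**Figure D3:**
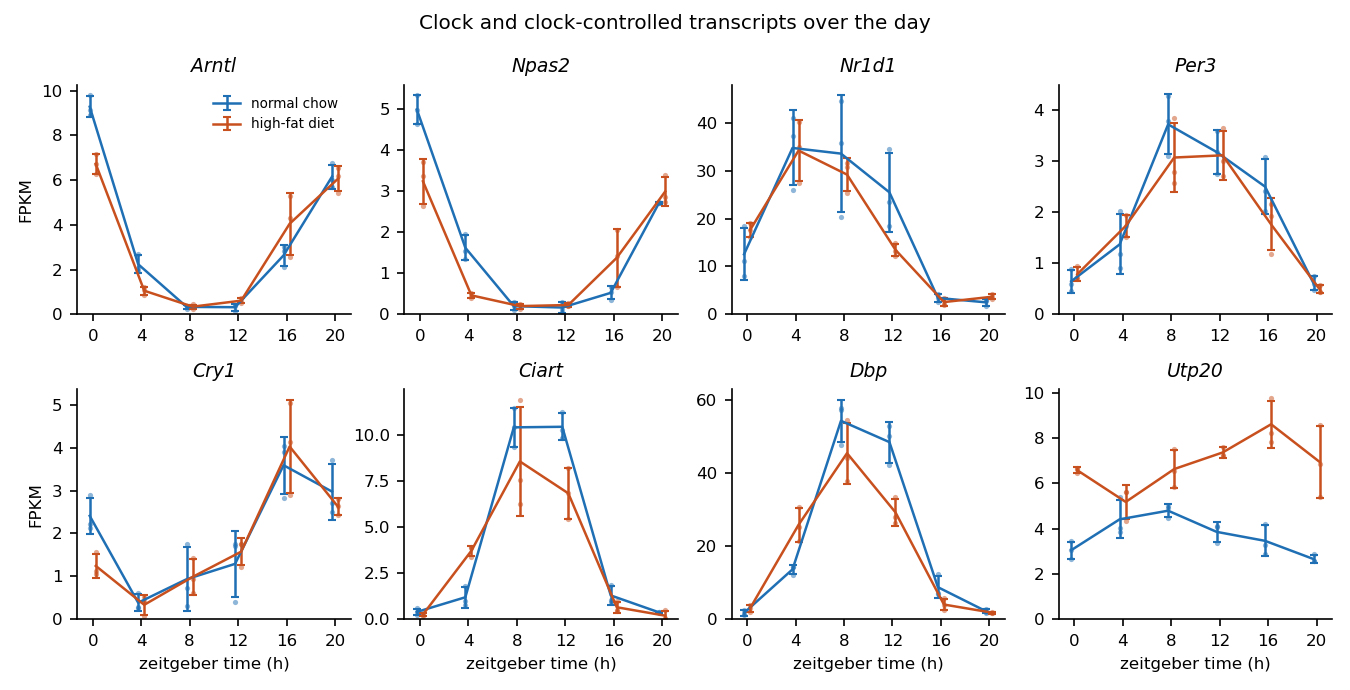
FPKM against zeitgeber time in h for 6 clock genes, Dbp and Utp20. Points are libraries, lines join means of 3 mice and bars are SD. Arntl fell from 9.28 FPKM at ZT0 to 0.316 FPKM at ZT12 under normal chow.

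Outside the clock list, Dbp, a clock-driven transcription factor, had the widest rhythm under both diets, with peak-to-trough differences of 5.18 ± 0.20 and 4.82 ± 0.23 log2 (SE). Under normal chow it was followed by Nfil3 (3.65), a repressor that opposes Dbp, the nuclear receptor Ppard (2.98), Cml5 (2.60), the endoplasmic reticulum protein Sdf2l1 (2.20), the uridine phosphorylase Upp2 (2.11), the lactate and pyruvate transporter Slc16a1 (2.01), Ndrg1 (1.92), the glucocorticoid-induced Tsc22d3 (1.91) and Palm3 (1.84). Under the high-fat diet the others were Cyp24a1 (2.56), which inactivates vitamin D, Ppard (2.28), Slc16a1 (1.94), Ndrg1 (1.55), Palm3 (1.52), Tsc22d3 (1.49), the kinase Sgk1 (1.43), Sdf2l1 (1.41) and Tsku (1.39). Cyp24a1 and Sgk1 did not pass under normal chow (adjusted p = 0.276 and 0.0802), yet their rhythms did not differ between diets by the test of the difference (adjusted p = 1.00 for both).

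Clock output genes were rhythmic in 10 of 11 cases under each diet, or 11 of 11 adjusted over the list alone (adjusted p = 2.74e-09 and 7.30e-10). Tef, a relative of Dbp, had a peak-to-trough difference of 1.79 and 1.30 log2, and the deubiquitinase Usp2 of 1.52 and 1.21. Of 18 heat shock and cold-inducible genes 9 and 11 were rhythmic, or 12 and 17 adjusted over the list alone (adjusted p = 2.22e-05 and 6.74e-08). The cold-inducible Cirbp peaked at 6.89 h and 6.47 h, and the chaperone Hspa5 at 19.5 h and 19.3 h. Of 17 unfolded protein response genes 9 and 8 were rhythmic, or 9 and 9 adjusted over the list alone (adjusted p = 1.59e-05 and 7.29e-05).

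Other lists passed under a single diet, and the difference of these shares between diets was not tested. Under normal chow 7 of 22 sterol synthesis genes were rhythmic, or 14 adjusted over the list alone (adjusted p = 0.00706), among them Fdps and Msmo1, enzymes of the pathway, with peaks at 22.8 h and 21.9 h. The high-fat values were 5 and 11 (adjusted p = 0.0829). The normal chow share was not counted again without the libraries with adrenal transcripts, which lie at ZT0, ZT4 and ZT16. Matrix genes had 5 of 12 rhythmic under normal chow, or 7 adjusted over the list alone (adjusted p = 0.00815), including the collagens Col4a1 and Col3a1. Under the high-fat diet they had 3 and 3 (adjusted p = 0.139). Under the high-fat diet 13 of 34 loop, distal and collecting duct transport genes passed, or 15 adjusted over the list alone (adjusted p = 2.90e-06). The normal chow values were 6 and 8 (adjusted p = 0.153). Glucocorticoid response genes had 6 of 12 under the high-fat diet, also 6 adjusted over the list alone (adjusted p = 0.000544), and 4 and 7 under normal chow (adjusted p = 0.0541). NAD genes had 6 of 18 and 9 adjusted over the list alone (adjusted p = 0.00641), against 3 and 5 (adjusted p = 0.3498).

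Across all 11144 genes 866 (7.77%) were rhythmic under normal chow and 813 (7.30%) under the high-fat diet. Both lists held 389 genes, where independent lists of these sizes would share 63.2. Their median peak-to-trough change was 1.53-fold and 1.46-fold. Peaks of 173 normal chow genes and 89 high-fat genes fell between 0 and 4 h, 253 and 233 between 4 and 8 h, and 126 and 190 between 8 and 12 h. The windows from 12 to 16 h, 16 to 20 h and 20 to 24 h held 71 and 45, 46 and 79, and 197 and 177, and the difference between these distributions was not tested. The counts for normal chow and the high-fat diet depended on the fit: 375 and 3166 with time as a factor, 568 and 470 by a rank test, 1627 and 647 in a fit over all 36 libraries, 1301 and 1217 after GC correction, and 935 and 1307 with an alternating term. With the replicate block they were 688 and 446. Without the 4 libraries with adrenal transcripts they were 515 and 810, and without ZT0 and ZT4 270 and 259.

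Rhythms differed between diets for 3 genes. Dbp peaked 1.46 ± 0.247 h earlier under the high-fat diet, at 8.24 h against 9.71 h (adjusted p = 0.0249), and Npas2, a partner of BMAL1, 2.01 ± 0.357 h earlier, at 21.2 h against 23.2 h (adjusted p = 0.0302). Utp20, a factor of ribosome assembly, peaked 7.61 ± 1.08 h later, at 15.6 h against 7.96 h (adjusted p = 0.0249), with small peak-to-trough differences of 0.53 ± 0.12 and 0.70 ± 0.12 log2. Dbp lies on chromosome 7 from 45705088 to 45710203, Npas2 on chromosome 1 from 39193731 to 39363236 and Utp20 on chromosome 10 from 88746607 to 88826804. At an unadjusted p under 0.05 there were 353 genes, fewer than the 557.2 that chance gives. Of the 477 genes past the threshold under normal chow alone and the 424 under the high-fat diet alone, 0 and 0 differed by this limma test (90 and 39 at an unadjusted p under 0.05). With time as a factor 2 genes differed, with the replicate block 0, and with the block after GC correction 1. The count of 3 became 0 without ZT0 and ZT4, 0 without any of the high-fat ZT4 replicates 3, 4 or 5 or ZT16 replicates 1 or 4, and 1 without the normal chow ZT0 replicate 4 or ZT16 replicates 1 or 5.

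Peaks of clock genes were earlier under the high-fat diet. Over 12 clock genes rhythmic in the pooled fit the median difference was -1.29 h (jackknife SE 0.330, permutation p = 0.01), and 11 of 12 were earlier. Arntl differed by -1.30 ± 0.291 h (SE), Nr1d1 by -1.27 ± 0.433 h, Ciart by -1.34 ± 0.378 h and Cry1 by -1.59 ± 0.737 h. Of these clock genes Npas2 alone passed the test of a different rhythm, while Arntl had an adjusted p of 0.382. Other measured clock genes had differences of -1.15 h for Nr1d2, -0.950 h for Per3, -0.901 h for Per2, -0.546 h for Per1 and 0.0626 h for Cry2, and wide errors were seen for Clock (-2.56 ± 2.01 h), Bhlhe40 (-3.49 ± 1.59 h) and Rora (1.23 ± 2.09 h). Over all 1634 pooled rhythmic genes the median was -0.464 h (jackknife SE 0.353, permutation p = 0.18), which did not pass. It passed the same permutation test with upper quartile rescaling (-0.629 h, p = 0.04), after GC correction (-0.620 h, p = 0.04), for genes past the threshold in each diet (-0.771 h, p = 0.01) and without the high-fat ZT0 replicate 4 (-0.644 h, p = 0.01). Without ZT0 and ZT4 it was -0.229 h, and after GC correction with the replicate block -0.527 h (permutation p = 0.47 and 0.1).

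**Figure D4:**
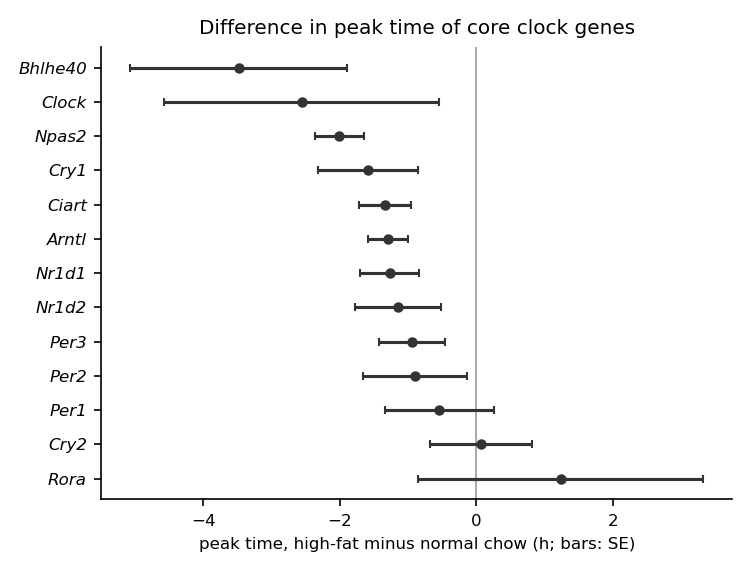
Peak time under the high-fat diet minus normal chow, in h, for 13 of the 14 measured core clock genes, with bars for SE. Arntl lies at -1.30 h and Rora, with a wide bar, at 1.23 h.

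Amplitudes were smaller under the high-fat diet, with a median ratio of 0.824 over the 1634 genes (log2 ratio -0.28, jackknife SE 0.12, permutation p = 0.01), and 70.4% of these genes had the smaller value. Clock genes had a median ratio of 0.939 (permutation p = 0.28). The call was lost without ZT0 and ZT4 (-0.09, permutation p = 0.39). It was also lost without the normal chow ZT8 replicate 1 (-0.27, permutation p = 0.05), the high-fat ZT12 replicate 4 (-0.26, p = 0.06) or ZT20 replicate 4 (-0.22, p = 0.11).

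Averaged over the day, Rarres2, which encodes the secreted protein chemerin, showed the largest rise under the high-fat diet among the named genes. It went from 77.3 ± 39.8 to 247 ± 34.5 FPKM (SD, n = 18 each; log2 change 1.78 ± 0.13 SE, adjusted p = 7.35e-11). The glucuronosyltransferase Ugt2b37 rose from 51.6 to 158 FPKM (1.66 ± 0.11), the ATP carrier Slc25a25 from 17.6 to 44.3 FPKM (1.43 ± 0.14) and Ttr, a carrier of thyroid hormone, from 85.2 to 216 FPKM (1.42 ± 0.14). Lep, the fat hormone leptin (1.69), Ctxn3 (1.61), the prolactin receptor Prlr (1.59), the water channel Aqp4 (1.51) and the ubiquitin-like Ubd (1.29) also rose. The largest fall among the called genes was that of Cfd, the adipocyte protease adipsin, from 408 ± 275 to 16.0 ± 15.7 FPKM (-5.10 ± 0.50, adjusted p = 2.41e-08). Thrsp, a regulator of lipid synthesis (-2.39), the fat hormone Retn (-2.31), Adig (-2.23), the apolipoprotein Apoc1 (-2.12), the carboxylesterase Ces1g (-1.98), Cox8b (-1.98), the retinol carrier Rbp4 (-1.76), the carbonic anhydrase Car3 (-1.68) and Mrap (-1.64) fell as well. Of 15 measured adipocyte markers 9 fell and 1, Lep, rose. Cox8b had the widest error, with an SE of 0.65 and an adjusted p of 0.0347.

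In all, 1850 genes differed, 585 higher and 1265 lower (68.4% lower), with 60 and 108 of them changed at least 1.5-fold. The split depended on scaling, and the sources used here do not state whether both diets' tables came from 1 normalisation run. It was 50% lower with median ratio rescaling, 44.4% with upper quartile rescaling and 46.8% after GC correction. The count was 1512 without ZT0 and ZT4 and 940 with the adipocyte score as covariate, of which 894 were among the 1850. No count over all times is given without the adrenal libraries. There the normal chow group of ZT4 held only replicate 4, with its GC slope of -0.37.

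Sterol synthesis genes fell together. Of 22 measured members 16 fell and 1, the sterol demethylase Cyp51, rose, with the same counts adjusted over the list alone (median log2 change -0.39). Fdft1, squalene synthase, fell from 10.5 ± 2.76 to 7.21 ± 0.530 FPKM (-0.48 ± 0.06 SE), and Fdps, farnesyl diphosphate synthase, by 0.60 ± 0.08 on the log2 scale. The list passed limma's camera with its preset correlation (adjusted p = 8.37e-09). It did not with an estimated one (adjusted p = 0.0509 with an estimated correlation). In the same comparison adipocyte markers had a median of -0.71 (-0.47 without the normal chow ZT0 replicate 5 and -1.10 for the 12 at a mean FPKM of at least 5) and adrenal markers of -1.29 (-0.74 with the adipocyte score as covariate).

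Of 23 fatty acid synthesis genes 13 fell and 1, the acetate-activating Acss2, rose, or 14 and 1 adjusted over the list alone (median -0.36). Fads1, a desaturase, fell by 0.82 ± 0.07, Acaca, which makes malonyl-CoA, by 0.99 ± 0.11, Srebf1, the transcription factor of the pathway, by 0.72 ± 0.08 and Fasn, fatty acid synthase, from 22.7 ± 17.3 to 6.31 ± 1.66 FPKM (-1.53 ± 0.18). Camera gave an adjusted p of 2.83e-06 (adjusted p = 0.194 with an estimated correlation). Adipocytes express many of these genes, and with the adipocyte score as covariate 8 members fell, with a median of -0.18. At a mean FPKM of at least 5, with no covariate, 9 of 18 fell, with a median of -0.20.

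Genes of fatty acid oxidation and other PPARA targets had 12 of 37 members higher and 0 lower, or 16 and 5 adjusted over the list alone. With the adipocyte score as covariate 6 were higher and 0 lower, with a median of 0.08 in both fits. Without the normal chow ZT4 replicate 4 the counts were 15 and 4, with a median of 0.12 (also 0.12 with upper quartile rescaling), and 3 were lower without ZT8 replicate 1. Without any other single library 0 to 2 were lower. Vnn1, a pantetheinase, rose from 28.3 to 36.4 FPKM (0.37 ± 0.06), and the acyl-CoA enzymes Acadvl and Cpt2 by 0.17 ± 0.03 and 0.19 ± 0.04 log2 (camera adjusted p = 6.74e-06; adjusted p = 0.194 with an estimated correlation). Of 24 glucose metabolism genes 7 rose and 2 fell, or 10 and 3 adjusted over the list alone. Pck1, the rate-limiting enzyme of gluconeogenesis, rose from 499 ± 165 to 1157 ± 298 FPKM (1.24 ± 0.09, adjusted p = 1.00e-10), pyruvate kinase Pklr from 11.2 to 17.3 FPKM (0.60 ± 0.06), and Pcx and Fbp1 by 0.29 ± 0.04 and 0.24 ± 0.03 (camera adjusted p = 0.000276; adjusted p = 0.229 with an estimated correlation). Of 24 citric acid cycle genes 5 rose and 2 fell, also 5 and 2 adjusted over the list alone, the largest being Aco1 (0.27 ± 0.03) (camera adjusted p = 0.000382; adjusted p = 0.264 with an estimated correlation). Oxidative phosphorylation genes had 0 of 46 higher and 3 lower, or 0 and 1 adjusted over the list alone (camera adjusted p = 0.934), with a negative median and mean (both -0.02) and a positive direction in the test.

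Of 6 measured MHC class II genes 5 rose, also 5 adjusted over the list alone, with H2-Ab1 from 100.2 to 129.98 FPKM (0.37 ± 0.08) and the invariant chain Cd74 from 248 to 326 FPKM (0.39 ± 0.09) (camera adjusted p = 1.05e-05; adjusted p = 0.229 with an estimated correlation). Of 10 macrophage and inflammation genes 4 rose (7 without the adrenal libraries, and 2 without ZT0 and ZT4, without the high-fat ZT0 replicate 4 or at a mean FPKM of at least 5), or 7 adjusted over the list alone, led by the chemokines Cxcl10 (0.67 ± 0.11) and Ccl2 (0.61 ± 0.13) (camera adjusted p = 7.08e-06; adjusted p = 0.194 with an estimated correlation). Of 14 interferon response genes 6 rose (3 of 7 at a mean FPKM of at least 5), or 7 adjusted over the list alone, including Oas1a (0.41 ± 0.07) and Irf7 (0.43 ± 0.09) (camera adjusted p = 7.08e-06; adjusted p = 0.194 with an estimated correlation). Of 4 lymphocyte genes 3 rose, also 3 adjusted over the list alone (camera adjusted p = 0.0233; adjusted p = 0.198 with an estimated correlation).

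**Figure D5:**
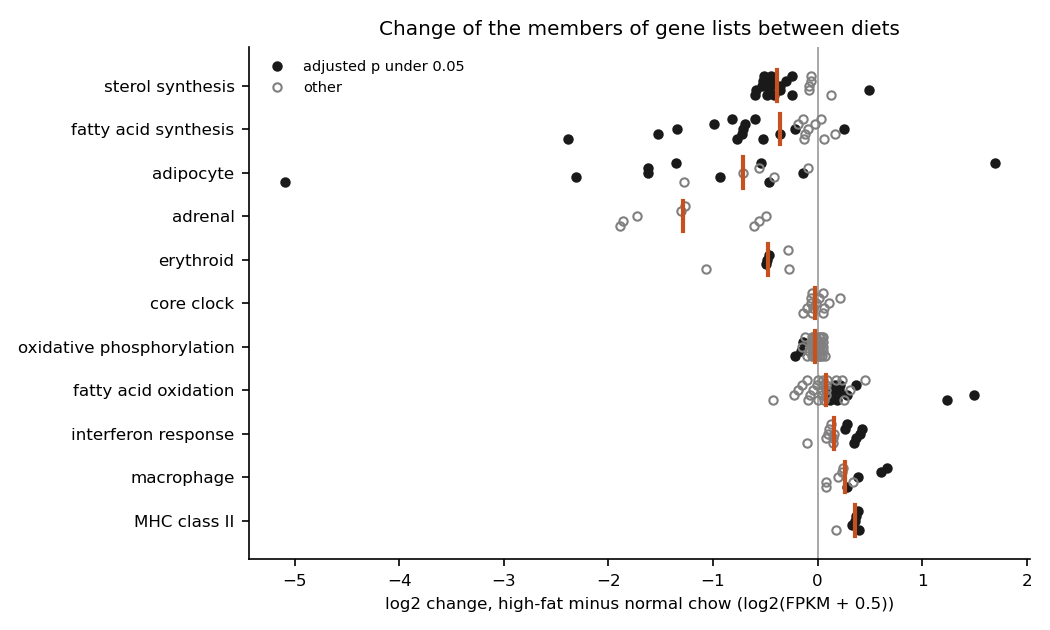
Log2 change between diets, high-fat minus normal chow, on the log2(FPKM + 0.5) scale, for members of 11 gene lists. Each point is a gene, filled where the adjusted p was under 0.05, and the vertical bar is the list's median, -0.39 for sterol synthesis and 0.36 for MHC class II.

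Among markers of other tissues, 9 of 15 adipocyte genes fell and 1, Lep, rose, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.000241; adjusted p = 0.383 with an estimated correlation). Of 8 adrenal genes 0 passed, or 5 lower adjusted over the list alone (camera adjusted p = 0.0613), and over all genes 5 were lower without any one of the normal chow ZT0 replicates 1 or 4 or ZT4 replicate 4. Of 6 erythroid genes 3 fell, or 5 adjusted over the list alone, among them the haem enzyme Alas2 (-0.47 ± 0.12) (camera adjusted p = 0.0103; adjusted p = 0.291 with an estimated correlation). With the adipocyte score as covariate 0 erythroid genes passed limma's test, with a median of -0.33 against -0.47 without it. There were 5 lower without the normal chow ZT0 replicate 5 or ZT4 replicate 2, and 2 without the adrenal libraries or without ZT0 and ZT4. Of 14 androgen-dependent or sex-dimorphic kidney genes 4 rose and 1 fell, or 5 and 1 adjusted over the list alone. The list was led by Prlr and the dipeptidase Cndp2, which fell from 1314 to 845 FPKM. Camera gave an adjusted p of 0.0180 (adjusted p = 0.291 with an estimated correlation). The list was not split by sex bias, so its upward direction is no measure of androgen action.

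Among kidney transport lists, 9 of 31 proximal tubule genes fell and 5 rose, or 13 and 7 adjusted over the list alone. The amino acid transporter Slc7a7 fell from 81.1 to 46.1 FPKM (-0.80 ± 0.08) and the phosphate transporter Slc34a3 by 0.61 ± 0.07, while the dicarboxylate transporter Slc13a3 rose by 0.39 ± 0.04 log2 (camera adjusted p = 0.487). The proximal tubule list passed fry with a downward direction (adjusted p = 0.0228). Of 34 loop, distal and collecting duct genes 8 fell and 2 rose, or 9 and 3 adjusted over the list alone. Pvalb, a calcium-binding protein, rose from 43.4 to 68.2 FPKM (0.65 ± 0.05), and the sodium channel subunit Scnn1b fell by 0.26 ± 0.05 (camera adjusted p = 0.469). The 14 core clock genes had 0 changes in level, also 0 adjusted over the list alone (camera adjusted p = 0.499), with a negative median (-0.03) and a positive test direction. NAD genes had 3 of 18 higher and 3 lower, or 3 and 5 adjusted over the list alone (camera adjusted p = 0.679), also with a negative median (-0.02) and a positive direction. Heat shock genes (0 higher and 3 lower of 18, adjusted p = 0.499), unfolded protein response genes (1 and 2 of 17, adjusted p = 0.236) and cytochrome P450 and other drug-metabolising genes (5 and 2 of 19, adjusted p = 0.0613) had a positive median and test direction and a negative mean. Their counts adjusted over the list alone were 0 and 3, 1 and 2, and 5 and 2.

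At single times, 177 genes differed at ZT0, 179 at ZT4, 37 at ZT8, 41 at ZT12, 62 at ZT16 and 29 at ZT20. At ZT0 71 were higher and 106 lower, at ZT4 53 and 126, and with upper quartile rescaling these became 126 and 58, and 148 and 53. The transcribed pseudogene 9030619P08Rik, whose reads could be shared with related genes, was lower at all 6 times, for example 9.43 ± 2.69 against 43.9 ± 7.77 FPKM (SD, n = 3) at ZT4 (limma log2 change -2.18 ± 0.20 SE, adjusted p = 8.72e-08). Ugt2b37 was higher at ZT0 (2.00 ± 0.28), ZT4 (1.75) and ZT20 (1.76), Rarres2 at ZT8 (1.95 ± 0.32), ZT12 (2.01) and ZT16 (2.07), and the oxygen-sensing hydroxylase Egln3 at ZT0 (1.35 ± 0.18) and ZT8 (1.15). Slc13a3 was higher at ZT4 (0.77), and Utp20 at ZT12 (0.86), ZT16 (1.21) and ZT20 (1.22 ± 0.14). Lower values were found for Fads1 at ZT0 (-1.32 ± 0.16), Acaca at ZT4 (-1.86 ± 0.26), Gm15441 at ZT8 (-2.03), and the calcium-binding S100g at ZT12 (-1.13) and ZT20 (-1.06). Only the 2 genes with the smallest p per direction were taken at each time, so these genes may also differ at times not given. Leaving out single libraries moved the counts from 77 to 368 at ZT0, 49 to 1807 at ZT4, 13 to 52 at ZT8, 13 to 63 at ZT12, 9 to 93 at ZT16 and 9 to 47 at ZT20. Without ZT0 and ZT4 the counts were 110 at ZT8, 105 at ZT12, 130 at ZT16 and 66 at ZT20. Without the adrenal libraries they were 269, 78, 92, 60 and 52 at ZT0, ZT8, ZT12, ZT16 and ZT20. No count is given at ZT4, where 1 normal chow library was left and the spread would come from other groups. After GC correction the counts were 291, 318, 59, 73, 98 and 47 from ZT0 to ZT20. The adipocyte score as covariate gave 53 at ZT4, 21 at ZT12 and 17 at ZT20. Counts at different times are not a test of a difference between times, which 2 genes passed (307 at an unadjusted p under 0.05).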

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

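Of the tests here, those of an offset in collection time and of a single library, and the clock median itself, were chosen after the results were seen. The GC test was set before its result. Dbp, Npas2 and Utp20 had a 24-h rhythm that differed between diets by the test of the difference itself, which brought them here. The peak of Dbp differed by -1.46 h, that of Npas2 by -2.01 h and that of Utp20 by 7.61 h (adjusted p = 0.0249, 0.0302 and 0.0249). Of 100 groupings only the actual one gave as many as 3 genes, and the highest of the other 99 gave 1. That gap is small, and 353 genes had an unadjusted p under 0.05 in limma, where chance gives 557.2. Chance is therefore not excluded for the count of 3. With the replicate block the count was 0, and with the block after GC correction 1. The count was 0 without ZT0 and ZT4, 0 without any of the high-fat ZT4 replicates 3, 4 or 5 or ZT16 replicates 1 or 4, and 1 without the normal chow ZT0 replicate 4 or ZT16 replicates 1 or 5.

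The earlier peaks of clock genes (median -1.29 h) were set against technical explanations. A single library was argued against, because the median nearest 0 without any one library was -1.12 h. A GC trend between libraries was argued against as well, since the median was -1.35 h after its removal. A uniform offset in the time of collection was not excluded: the other rhythmic genes had a median of -0.441 h that did not pass (permutation p = 0.2), and clock genes differed from them by -0.845 h, past 2 jackknife SE (0.384) but with a permutation p of 0.07. An effect of the diet on the clock stays open beside it.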

How the results depend on the processing

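Corrections for GC, adrenal libraries, the adipocyte score, ZT0 and ZT4 and the alternating term were chosen after the data were seen. No called level change or phase difference of a named gene changed its sign under any alternative run. A peak-to-trough difference is always positive, so for rhythms within a diet a change of sign was not possible. Calls of named genes were lost, however: 28 lost, 1 gained and 146 on the same side with the adipocyte score; 26, 3 and 179 without ZT0 and ZT4; 17, 4 and 200 without the adrenal libraries; 0 to 11 lost with each other alternative run on them. The clock median stayed between -1.49 and -1.12 h. The majority of lower level calls did not hold: 585 higher and 1265 lower became 836 and 836 with median ratio rescaling, 905 and 724 with upper quartile rescaling and 1120 and 985 after GC correction. With the first 2 the 71 and 106 at ZT0 became 113 and 74, and 126 and 58, and the 53 and 126 at ZT4 became 118 and 63, and 148 and 53. Where a result moved, the cause was not tested unless stated. Depth in reads is unknown, which limits statements on low genes.

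Replicate numbers showed at most a weak pairing of the libraries. Over 119 same-numbered pairs deviations correlated with a median of 0.0384 (range -0.605 to 0.477), against -0.0040 for different numbers. Of the same-numbered pairs 32.8% were over 0.1, and 12 of 36 libraries correlated best with their own number. Some pairing is therefore not excluded. With the replicate block 446 genes were rhythmic under the high-fat diet, 0 differed in rhythm, and 41 and 14 differed at ZT16 and ZT20; with GC correction and the block 1 differed in rhythm, and the phase difference was -0.527 h (permutation p = 0.1).

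Without a filter ZT16 gave 38 genes and 20 lists passed; at a mean FPKM of at least 5 (fewer genes) ZT4 gave 117. Median ratio rescaling gave 18 at ZT20. Upper quartile rescaling gave 38 at ZT16, 14 at ZT20 and a phase difference of -0.629 h. GC correction gave 291, 318, 59, 73, 98 and 47 genes at ZT0 to ZT20, 1301 rhythmic genes under normal chow and a phase difference of -0.620 h. Without the adrenal libraries (fewer samples) the counts were 269 at ZT0, 4929 at ZT4, where only normal chow replicate 4 with its GC slope of -0.37 remained, 78 at ZT8, 92 at ZT12, 52 at ZT20 and 515 rhythmic under normal chow. The adipocyte score gave 940 genes, and 53, 21 and 17 at ZT4, ZT12 and ZT20. Without ZT0 and ZT4 the counts were 110, 105, 130 and 66 at ZT8 to ZT20, 270 and 259 rhythmic, 0 different rhythms and an amplitude ratio of -0.0861 log2. The alternating term gave 1307 rhythmic genes under the high-fat diet. For normal chow, time as a factor gave 375 rhythmic genes, the rank test 568 and the fit over all libraries 1627; for the high-fat diet they gave 3166, 470 and 647. Genes past the threshold in each diet had a phase difference of -0.771 h.

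Leaving out each library in turn gave 1573 to 2751 genes with a different level and 77 to 368 at ZT0, 49 to 1807 at ZT4, 13 to 52 at ZT8, 13 to 63 at ZT12, 9 to 93 at ZT16 and 9 to 47 at ZT20. At ZT4 the extremes came without the high-fat replicate 4 (49) and the normal chow replicate 2 (1807), with 115 and 80 without normal chow replicate 3 and high-fat replicate 5. At ZT0 they came without high-fat replicate 3 (77) and normal chow ZT4 replicate 4 (368), with 94 without high-fat replicate 4. Within their own times, leaving out normal chow replicates 1, 4 and 5 gave 22, 19 and 16 at ZT8 and high-fat replicates 1 and 5 gave 13 and 14. At ZT12 normal chow replicates 2, 3 and 5 gave 22, 14 and 14 and high-fat replicates 2, 4 and 5 gave 20, 13 and 16. At ZT16 normal chow replicates 1, 4 and 5 gave 9, 22 and 19 and high-fat replicates 1, 3 and 4 gave 14, 32 and 41. At ZT20 normal chow replicates 1 and 5 gave 15 and 10 and high-fat replicates 1, 3 and 4 gave 11, 11 and 9. Without the normal chow ZT4 replicate 4 the counts were 63 at ZT12 and 47 at ZT20. There were 11 to 15 lists, 603 to 1146 and 606 to 814 rhythmic genes, and 0 to 4 different rhythms. The phase difference ranged from -0.644 to -0.328 h, that of the clock genes from -1.39 to -1.12 h, and the amplitude ratio from -0.31 to -0.22 log2.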

Other observations

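Single genes of 4 further lists rose or fell, while none of the 4 lists passed camera. By fry the oxidative stress list passed with a downward direction (adjusted p = 0.000326), while the amino acid, glucocorticoid and tubular injury lists did not. Every list that passed camera with its preset correlation also passed fry. No list passed camera with an estimated correlation. Of 18 oxidative stress genes 5 fell and 1 rose, or 6 and 1 adjusted over the list alone, with the glutathione transferase Gsta3 falling from 105 to 65.3 FPKM (-0.69 ± 0.05 SE, n = 18 each) and the haem oxygenase Hmox1 from 34.6 to 27.3 FPKM (camera adjusted p = 0.0815). Of 43 amino acid genes 10 fell and 5 rose, or 11 and 8 adjusted over the list alone (camera adjusted p = 0.867). The serine synthesis enzyme Phgdh fell from 8.94 to 5.07 FPKM (-0.68 ± 0.11). Among 12 glucocorticoid response genes the metallothioneins Mt1 and Mt2 fell, from 284 to 163 and from 109 to 59.3 FPKM, and Lcn2, Errfi1 and Dusp1 rose, with 3 higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.308). Of 8 tubular injury genes 4 rose and 3 fell, also 4 and 3 adjusted over the list alone (camera adjusted p = 0.466).

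The tests of alternation between consecutive times, and the splits for phase and amplitude, were chosen after the results were seen, as was the rule that a margin must exceed 2 jackknife SE. The sterol and fatty acid tests were set before their results.

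Lower sterol synthesis genes were set against tissue carried along with the kidney. With the adipocyte score as covariate the median was -0.44 against -0.39 without it, and without the adrenal libraries -0.38. These values argue against a smaller amount of fat and against adrenal tissue as the whole cause. The score follows the amount of adipocyte transcripts (Adipoq, Plin1 and Cidec). It would not remove a fall of sterol genes within adipocytes, which was not tested. The margins over 0.5 of the median were 0.25 ± 0.07 and 0.18 ± 0.04 (jackknife SE). The second SE came from leaving out 31 libraries in turn. It does not cover normal chow ZT4 replicate 4, the only library left in its group. A response to the diet is a hypothesis. For fatty acid synthesis genes the covariate moved the median from -0.36 to -0.18, with a margin of 0.0031 ± 0.0956, and a filter at a mean FPKM of at least 5, which left 18 of the 23 genes, moved it to -0.20 with no covariate, so less adipose tissue in the high-fat libraries could account for part of it and cannot be told apart from a change in kidney cells. After removal of the GC trend 77.0% of the 1850 genes were still called, so that trend was not the whole cause of the differences in level.

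High-fat libraries at ZT0, 8 and 16 differed from those at ZT4, 12 and 20 in 2113 genes, of which 1829 were higher at the former, against 5 genes under normal chow. The difference between diets reached 0 genes in limma (489 at an unadjusted p under 0.05), so the alternation is not shown to be specific to the diet. After removal of the GC trend 522 genes passed, 261 higher and 261 lower, with 17.8% of the 2113 still called, and the slopes over GC were -0.12 and 0.05 (exact permutation p = 0.00037). Relative depth was 1.06 and 0.776 (exact permutation p = 0.0313). Both exact tests permuted single libraries, 9 against 9, and not whole times, so they do not measure the spread between times. A library effect of GC or depth is consistent with these values, while batches that follow alternate times and an 8-h rhythm cannot be told apart at this sampling, and the labels give no batch.

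Other groupings of the libraries were also tested, 99 random ones plus the actual one. Chance can be excluded for the 866 and 813 rhythmic genes (highest other 1 and 126) and the 1850 genes with a different level (highest other 2), each reached by 1 of 100. For the amplitude difference of 0.279 in the log2 ratio the count was also 1 of 100, but by a margin over the highest other (0.276) far within the jackknife SE of 0.12. That call was lost without ZT0 and ZT4 (-0.09, permutation p = 0.39) and without the normal chow ZT8 replicate 1 (-0.27, p = 0.05), the high-fat ZT12 replicate 4 (-0.26, p = 0.06) or ZT20 replicate 4 (-0.22, p = 0.11). Chance cannot be excluded for the 12 gene lists called by camera, as 15 of 100 groupings gave as many and the highest other gave 19. Nor can it for the phase difference of 0.464 h over all pooled genes, reached by 18 of 100 with a highest other of 0.754 h. At a single time 10 splits of 6 libraries cannot give a share under 0.05. The actual counts and highest others were 177 and 0 at ZT0, 37 and 0 at ZT8, 41 and 0 at ZT12, 62 and 1 at ZT16, and 29 and 1 at ZT20. At ZT4 4 splits gave at least the actual 179 genes and the highest other gave 2083, which points to a structure among those libraries.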
